A study of Mus musculus with 28 samples.

How the data were processed

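RNA of mouse bone marrow-derived macrophages was measured on 28 Affymetrix whole-genome mouse arrays in 7 groups of 4, which the series' design text describes as biological replicates. The compound experiment held 16 arrays in 4 groups, and the siRNA experiment held 12 arrays in 3 groups. The deposited table held 1 log2 value per probe set and array, made with RMA (background correction, normalization between arrays and summary over probes) per the submitters' processing notes, with its version not given in the sources used here. The values ran from 1.77 to 15.23 in the compound experiment and from 1.86 to 15.24 in the siRNA experiment. Array medians lay between 5.61 and 5.71 in the first and between 5.91 and 5.96 in the second, so the experiments appear to have been normalized apart, and every test stayed within 1 experiment. RMA summaries shrink differences between dim probe sets, so fold changes of low values can understate the change. No pair of arrays held identical values (0 pairs).

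Probe sets were named from the platform annotation. Of 45101 probe sets, 35890 were listed with a gene and 9211 had none. Of those listed, 932 named several genes and were not used for genes, and 34945 named 1 gene and were not among the 64 control probe sets. Of these, 34741 matched a gene identifier of the RefSeq table of assembly GRCm38.p6 and 204 did not. That table changed 0 symbols and served only for names and for the order of genes along a chromosome, since the files give no build. Each of 18193 genes was represented by the probe set with the highest mean over all 28 arrays. A choice among several probe sets was needed for 9010 genes, and 9183 genes had 1 probe set.

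Each experiment was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group, eBayes without trend). Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 over the 18193 genes passed the threshold. The 7 comparisons were RA839 against DMSO in WT and in KO, the difference between these responses (an interaction term), KO against WT in DMSO, each Keap1 siRNA against the control siRNA, and siKeap1-1 against siKeap1-2. Fixed gene lists, 28 of pathways or responses and 9 of cell type markers, were written from textbook knowledge and tested with camera at a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the 37 lists of a comparison. Members past the threshold were counted over all genes and adjusted over the list alone. The NRF2 core list shares members with the other redox lists by construction, so those lists do not give separate evidence. The samples, tests, lists, rule for named genes and most alternatives were chosen before the data were examined. That rule named Nfe2l2, Keap1 and 7 Nrf2 target genes in every comparison. It added the 10 largest rises and 10 largest falls among genes past the threshold with no overlap between the groups' 4 arrays each (5 and 5 for the interaction and for the comparison of the siRNAs). It further added up to 4 members of each list past the threshold, and for the shared changes the 10 highest and 5 lowest genes by mean. Predicted genes with only a clone name were counted and not named.

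Same-numbered arrays deviated together within a genotype (correlations across genes of 0.30 to 0.66 in WT and 0.86 to 0.88 in KO) and within the siRNA experiment (0.27 to 0.85), each pair above the minimum of 0.1 set in advance. The numbers come from the labels, which do not say what they share. Between genotypes the numbers did not pair the arrays (−0.42 to −0.07 in DMSO). A block for the replicate number was therefore run as an alternative within each genotype and within the siRNA experiment, and its value is printed where it changed a result. Other values come from fits without it, which leave out this pairing and can overstate the spread. Other alternatives were a trended robust prior, all 28 arrays or only the groups compared in 1 fit, the brighter genes by mean and other choices of probe set. Further ones were quantile or median normalization, array weights, stricter thresholds, each array left out in turn, camera with an estimated correlation and fry. Comparisons that share control arrays were set beside 100 simulated draws of unchanged groups. These keep the gene-gene covariance of the residuals but not the pairing of same-numbered arrays.

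The procedure was tested on simulated arrays of 18193 genes with 50 genes drawn at random per fold size and changed upward and downward in turn. The simulated noise was independent between genes and between arrays. It held no pairing of arrays, so the shares below describe such arrays only. For RA839 in WT it recovered 52% of genes changed 1.5-fold, 82% at 2-fold, 98% at 3-fold and 98% at 4-fold, with 5 false calls. For the interaction the shares were 26%, 72%, 98% and 92%. For siKeap1-1 they were 72%, 86%, 96% and 100%. With no simulated change there were 0 calls. In the real KO compound arrays, setting arrays 1 and 2 against 3 and 4 gave 2722 calls, a structure the simulation lacks. Arrays have no read depth, and the 4 arrays per group limit the precision: the median standard error of a log2 fold change was 0.13 in the compound experiment, 0.0926 in the siRNA experiment and 0.184 for the interaction.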

Results

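Gene expression was profiled in macrophages grown from the bone marrow of C57BL/6 J mice aged 12 weeks. The study asked how these cells respond to RA839, a small molecule that binds Keap1, and whether the response needs the transcription factor Nrf2, the product of Nfe2l2. Keap1 holds Nrf2 in check by directing its degradation, and Nrf2 switches on genes of antioxidant defence and detoxification. In the compound experiment, cells with intact Nrf2 (WT) or without it (KO) received RA839 or the solvent DMSO at 0.2% for 4 h. In the siRNA experiment, WT cells received a control siRNA (siControl) or either of a pair of siRNAs against Keap1 (siKeap1-1 and siKeap1-2). Each of the 7 groups held 4 arrays. The design text once writes RA838 where every sample label writes RA839, and the dose of RA839, the siRNA sequences and the time after transfection are not given in the sources used here. Changes below are log2 fold changes ± standard error with n = 4 arrays per group and limma adjusted p-values, unless said otherwise.

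The targeted genes behaved as the labels state on every array. The Nfe2l2 probe set 1416543_at read 12.72 ± 0.20 (SD, n = 4) in WT with DMSO and 12.30 ± 0.32 in WT with RA839. It read 3.40 ± 0.11 in KO with DMSO and 3.27 ± 0.08 in KO with RA839, so KO lay −9.32 ± 0.14 from WT (adjusted p = 1.88e-16). The KO values lie where RMA does not tell weak signal from none, so the fall is a lower bound. The other Nfe2l2 probe set, 1457117_at, read 8.90 ± 0.22 in WT and 8.08 ± 0.17 in KO with DMSO. Which part of Nfe2l2 the KO allele lacks and which part this probe set covers is not given in the sources used here, so it checks nothing about the genotype. The Keap1 probe set 1450746_at read 11.09 ± 0.10 with siControl, 9.06 ± 0.09 with siKeap1-1 and 9.26 ± 0.15 with siKeap1-2. Keap1 mRNA thus fell 4.07-fold with siKeap1-1 (−2.03 ± 0.08, adjusted p = 5.24e-08), and with siKeap1-2 the change was −1.83 ± 0.08 (adjusted p = 1.42e-07). The other Keap1 probe set, 1450747_at, was dimmer, at 6.00 ± 0.12, 5.50 ± 0.15 and 5.67 ± 0.10 in the same order (−0.51 and −0.33, adjusted p = 0.00281 and 0.0369 over all probe sets). RA839 left Keap1 mRNA at 0.33 ± 0.10 above DMSO in WT (adjusted p = 0.207) and 0.01 ± 0.10 above it in KO (adjusted p = 1).

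**Figure D1:**
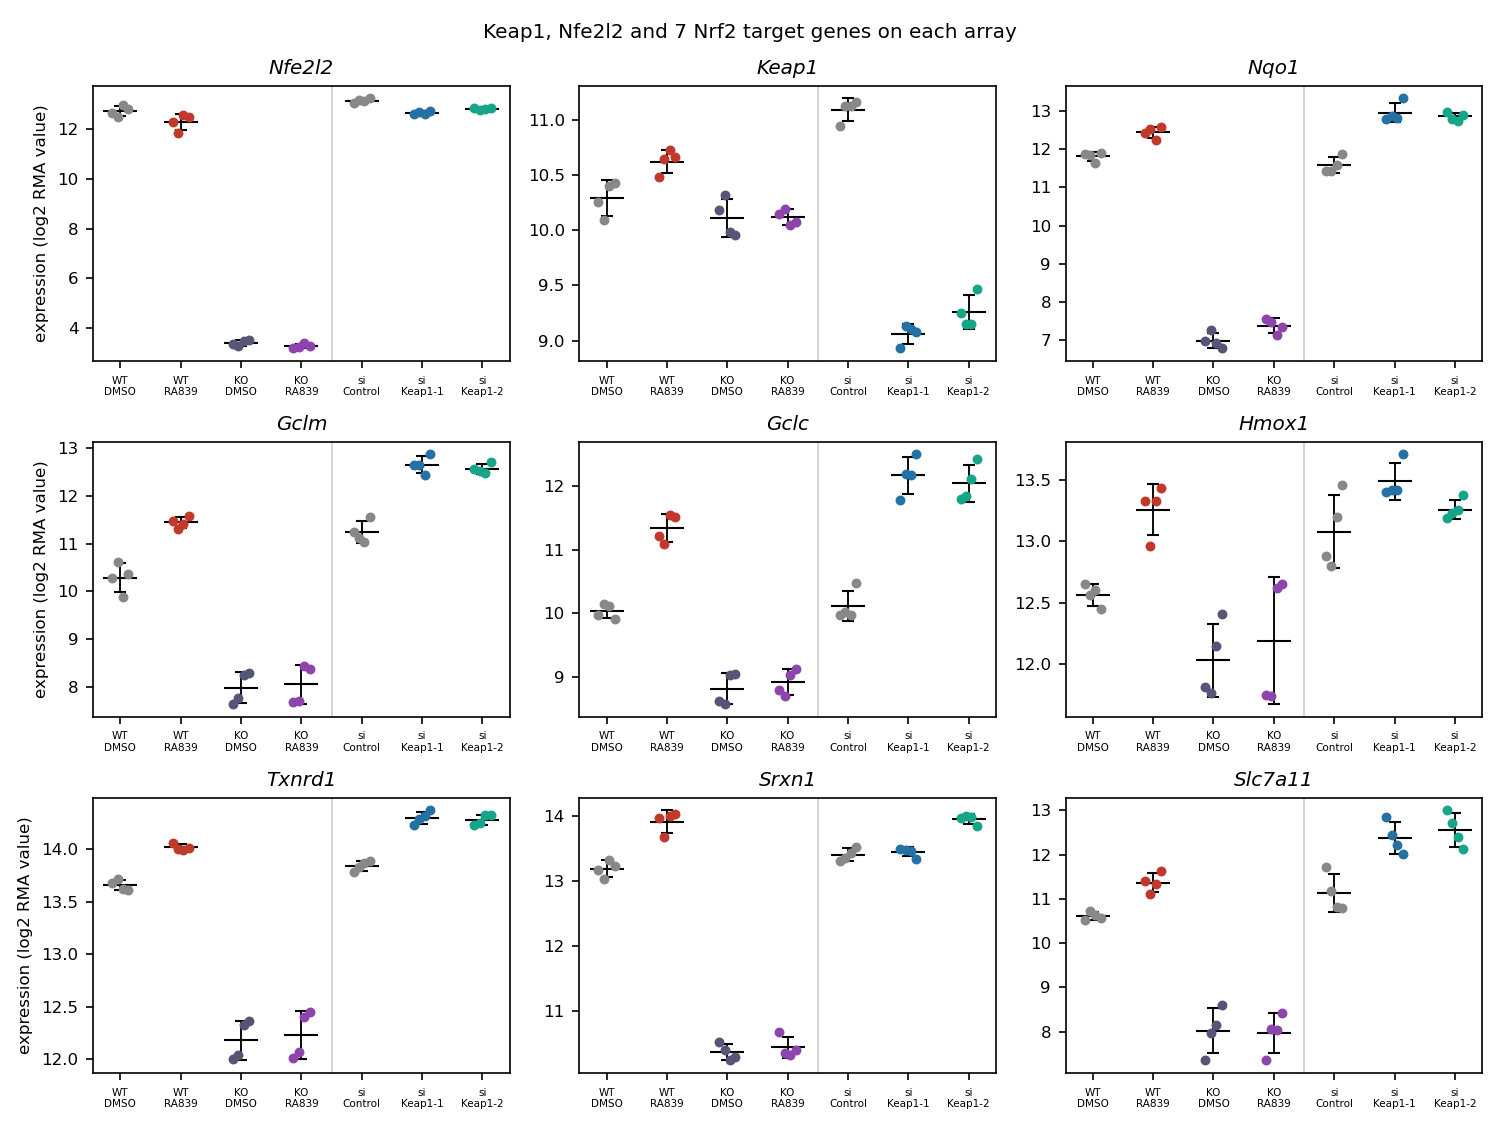
Each panel plots 1 gene, with log2 RMA values on the vertical axis and the 7 groups along the horizontal axis, points for arrays, wide marks for group means and bars for SDs (n = 4). Nfe2l2 lies near 12.72 in WT and 3.40 in KO with DMSO, and Keap1 lies at 11.09 with siControl and at 9.06 and 9.26 with the Keap1 siRNAs.

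RA839 raised 104 genes and lowered 16 in WT macrophages within 4 h, and genes of glutathione synthesis were among those raised. Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, rose 2.47-fold (1.31 ± 0.14, adjusted p = 0.000213). Its modifier subunit Gclm rose by 1.16 ± 0.20 (adjusted p = 0.0113), and Gss, the enzyme of the next step, by 1.46 ± 0.16 (adjusted p = 0.000279). Large rises were those of Ddit4l, a relative of the mTOR inhibitor Ddit4 (2.23 ± 0.21, adjusted p = 6.2e-05), Rasd2 (2.21 ± 0.33, adjusted p = 0.00283; 0.0614 with only the groups compared) and the chemokine Cxcl3 (2.18 ± 0.47, adjusted p = 0.049). Next came the matrix protein Comp (1.76 ± 0.22), the endothelin receptor Ednrb (1.76 ± 0.28), Fam13a (1.73 ± 0.23) and the membrane protein Cdcp1 (1.72 ± 0.22). They were followed by the lymphatic growth factor Vegfd (1.66 ± 0.19) and Prkaa2, a catalytic subunit of AMP-activated kinase (1.64 ± 0.27). In each of these genes all 4 RA839 arrays lay above all 4 DMSO arrays, and apart from Cxcl3 the adjusted p-values were at most 0.00656. A separation in either direction was seen in 1053 of the 18193 genes, where chance gives 2.86%. The ubiquitin ligase gene Trim9 had the highest value (2.61 ± 0.21, adjusted p = 3.09e-05), on a probe set type that can match more than 1 transcript; without such probe sets it was at 0.21 (adjusted p = 0.564). Of the 120 genes, 40 rose and 1 fell at least 2-fold. The gene that fell was Fst, the activin antagonist follistatin (−1.40 ± 0.18, adjusted p = 0.001), at −0.70 over the mean of its probe sets (adjusted p = 0.0823). The signalling adaptor Sla fell by 0.85 (± 0.13, adjusted p = 0.00409).

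Of 31 measured NRF2 core targets, 7 rose with RA839 in WT and 0 fell (17 and 0 adjusted over the list alone), and all 31 had a value above 0. Their median was 0.51 (camera adjusted p = 7.29e-20; adjusted p = 0.000227 with an estimated correlation). Srxn1, which restores oxidized peroxiredoxins, rose by 0.73 ± 0.11 (adjusted p = 0.00263). The quinone reductase Nqo1 rose by 0.63 ± 0.12 (adjusted p = 0.019), a call that ended without WT_DMSO array 1, 2 or 3 or WT_RA839 array 4 (0.57 to 0.65, adjusted p up to 0.0778). On the probe sets used, the other core genes named in advance did not pass without a block for the replicate number within genotype and did pass with it. They were the haem oxygenase Hmox1 (0.70 ± 0.21, adjusted p = 0.204, with the block 0.013), the thioredoxin reductase Txnrd1 (0.36 ± 0.11, adjusted p = 0.222, with the block 0.012) and the cystine transporter Slc7a11 (0.76 ± 0.23, adjusted p = 0.218, with the block 0.00626). A block for the number across genotypes, whose arrays the numbers do not pair, passed none of the 3 (adjusted p up to 0.192). A dimmer Txnrd1 probe set, 1424486_a_at, did rise without a block (1.23, adjusted p = 0.0257 over all probe sets). Another, 1424487_x_at (1.02, adjusted p = 0.067), and 1443536_at of Slc7a11 (1.37, adjusted p = 0.0768) did not pass. Nfe2l2 itself was at −0.42 ± 0.14 (adjusted p = 0.264, with the block 0.0198). Of 12 genes of glutathione synthesis, reduction and cystine uptake, Gclc, Gclm and Gss rose (4 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000105; adjusted p = 0.00826 with an estimated correlation).

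Further lists passed camera with RA839 in WT only at the preset correlation. The quinone, NADPH, ABC and AhR lists share members with the NRF2 core targets, among them Nqo1, Me1, Abcc1 and Abcc4. Among 18 genes of quinone and carbonyl detoxification 3 rose (6 rose and 2 fell adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.00525; adjusted p = 0.376 with an estimated correlation). Among 9 genes of NADPH supply and the pentose phosphate pathway 1 rose (3 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.00525; adjusted p = 0.0972 with an estimated correlation). Among 8 ABC export pumps the glutathione conjugate pump Abcc1 rose by 0.80 ± 0.13 (adjusted p = 0.00456, or 0.60 and 0.0917 over the mean of its probe sets). In the list 4 rose and 1 fell adjusted over the list alone, and Abcc4 was at 0.60 ± 0.14 (adjusted p = 0.0692, with the block 0.0148). The median of the pumps was 0.33 (camera adjusted p = 0.0149; adjusted p = 0.0791 with an estimated correlation). Among 7 AhR targets 1 rose, Nqo1, itself an NRF2 core target (1 adjusted over the list alone, median 0.37, camera adjusted p = 0.0149; adjusted p = 0.0791 with an estimated correlation). These 4 lists did not pass among the brighter genes alone (adjusted p = 0.0643 to 0.0883). Among 29 inflammatory cytokines and mediators the chemokine Cxcl3 rose (2.18 ± 0.47, adjusted p = 0.049) and the chemokine Ccl4 fell (−0.79 ± 0.16, adjusted p = 0.0332). Their median was −0.11 (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0342; adjusted p = 0.572 with an estimated correlation). Of 12 markers of neutrophils and their precursors 0 passed by limma over all genes or adjusted over the list alone, and their median was −0.33 (camera adjusted p = 0.0299, adjusted p = 0.572 with an estimated correlation). S100a8 was at −0.25 ± 0.09 (adjusted p = 0.34) and Ctsg at −0.40 ± 0.15 (adjusted p = 0.371). The inflammatory list did not pass without WT_DMSO array 2 or 3 or WT_RA839 array 1, 2 or 4 (adjusted p up to 0.229 over all 10 settings that ended its call). Nor did the neutrophil list without WT_DMSO array 3 or 4 or WT_RA839 array 2 or 4 (up to 0.104 over 8 such settings). The single calls of Cxcl3 and Ccl4 likewise ended without any of 12 and 7 arrays (adjusted p up to 0.158 and 0.102).

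The other 29 lists did not pass with RA839 in WT (camera adjusted p = 0.119 to 0.957, medians −0.23 to 0.11), among them 8 of the 9 marker lists. With the block 2 of them passed at the preset correlation, glutathione S-transferases (median 0.10, adjusted p = 0.0416) and antigen presentation (median −0.09, adjusted p = 0.0342). Without it an estimated correlation gave adjusted p = 0.572 and 0.946. The 3′ minus 5′ signal of the Gapdh control, a sign of RNA quality, was 3.74 on WT_RA839 array 2 and 0.77 to 1.00 on the other compound arrays. For the Actb control it was 3.1 on that array and 1.28 to 2.04 on the others. The other mouse controls of this kind did not stand apart on that array. The transferrin receptor was at 4.35 (3.37 to 4.37 on the others) and pyruvate carboxylase at 2.52 (0.36 to 2.75). Leaving out both WT arrays numbered 2 gave 103 genes, only 75 of them among the 120. In all, 1891 genes had an unadjusted p under 0.05, where chance gives 910. The count of 120 became 72 without WT_RA839 array 4, 74 without WT_DMSO array 1 and 486 (315 higher, 171 lower) with the replicate block within genotype.

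Without Nrf2, RA839 changed no gene past the threshold. In KO macrophages limma gave 0 genes for RA839 against DMSO, with 321 at an unadjusted p under 0.05 where chance gives 910, and a smallest adjusted p of 1. That fit leaves out the pairing of same-numbered KO arrays (correlations of 0.86 to 0.88). With the replicate block within genotype the count in KO was also 0. The 104 genes that rose in WT had a median of 0.87 there (quartiles 0.62 and 1.24) and of 0.04 in KO (quartiles −0.02 and 0.16). They were chosen for their rise in WT, which lifts the WT median. This contrast alone therefore does not show that the response needs Nrf2. In KO Gclc lay at 0.10 ± 0.14, Gclm at 0.07 ± 0.20, Srxn1 at 0.08 ± 0.11, Txnrd1 at 0.05 ± 0.11, Hmox1 at 0.16 ± 0.21, Slc7a11 at −0.06 ± 0.23 and Nqo1 at 0.39 ± 0.12 (adjusted p = 1 each). Nqo1 read 7.56, 7.48, 7.13 and 7.34 on KO_RA839 arrays 1 to 4. On the same-numbered KO_DMSO arrays it was lower each time, at 6.98, 7.25, 6.92 and 6.79. Beside its rise of 0.63 ± 0.12 in WT, a loss of the Nqo1 response in KO is not shown. The NRF2 core targets had a median of 0.02 in KO (camera adjusted p = 0.655), and none of the 37 lists passed camera in KO without the block (adjusted p = 0.119 to 0.989, medians −0.07 to 0.11). With the replicate block 3 lists passed in KO at the preset correlation and small medians: AhR targets (0.11, adjusted p = 0.0062), cholesterol synthesis (0.06, adjusted p = 0.00642) and macrophage markers (−0.05, adjusted p = 0.0265). Without the block an estimated correlation gave adjusted p = 0.589, 0.989 and 0.989 for them.

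By limma the response itself differed between genotypes for 21 genes, each responding more in WT than in KO. Chance was not excluded for this count, since 6 of 100 regroupings of the arrays within each genotype gave as many genes (highest other 1592). The difference was 2.17 ± 0.29 for Ddit4l (adjusted p = 0.00787) and 2.04 ± 0.31 for Comp (adjusted p = 0.018; up to 0.0511 without WT_RA839 array 4 or KO_RA839 array 1). It was 2.26 ± 0.40 for Ednrb (adjusted p = 0.0388) and 1.82 ± 0.31 for Cdcp1 (adjusted p = 0.0331), calls that ended without any of 13 and 12 of the 16 arrays (adjusted p up to 0.117 and 0.099). Over the mean of its probe sets Ednrb was at 0.92 (adjusted p = 0.0988), and with all 28 arrays in 1 fit its call was lost (0.095). The highest difference, 2.60 ± 0.29 for Trim9 (adjusted p = 0.00183), was 0.18 without probe sets that can match more than 1 transcript. For Gclc the difference was 1.21 ± 0.19 (adjusted p = 0.0237), lost without any of WT_DMSO arrays 1 and 3, WT_RA839 arrays 3 and 4, KO_DMSO arrays 3 and 4 and KO_RA839 arrays 1 and 2 (adjusted p up to 0.0765). The Gclc call was also lost with arrays centred on their medians (1.2, adjusted p = 0.0646). Without probe sets that can match more than 1 transcript the Gclc difference was of similar size and did not pass (1.28, adjusted p = 0.162). Gclm (1.09 ± 0.29, adjusted p = 0.461) and Srxn1 (0.65 ± 0.15, adjusted p = 0.241) differed between genotypes with the replicate block (adjusted p = 0.0306 and 0.0201). For Nqo1 the difference was 0.23 ± 0.17, for Hmox1 0.54 ± 0.29, for Txnrd1 0.31 ± 0.16 and for Slc7a11 0.81 ± 0.33 (adjusted p = 1 each). The NRF2 core targets as a list responded more in WT, with a median difference of 0.41 (1 past the threshold, 10 adjusted over the list alone, camera adjusted p = 3.09e-18; adjusted p = 0.000349 with an estimated correlation). So did the glutathione list, with a median of 0.14 (2 past the threshold, 3 adjusted over the list alone, camera adjusted p = 2.53e-05; adjusted p = 0.00493 with an estimated correlation).

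Lists whose difference between genotypes passed camera only at the preset correlation had 0 members past the threshold by limma over all genes. The first was NADPH supply (median 0.13, 2 adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.0895 with an estimated correlation). The others, in the same order of values, were quinone detoxification (0.19, 2, 0.0229, adjusted p = 0.652 with an estimated correlation) and ABC export pumps (0.22, 3, 0.0229, adjusted p = 0.0895 with an estimated correlation). The quinone list did not pass without WT_DMSO array 3, WT_RA839 array 1, 3 or 4, KO_DMSO array 2 or KO_RA839 array 3 (adjusted p up to 0.184 over all 8 settings that ended its call). Nor did the ABC list without WT_RA839 array 2 or 3, KO_DMSO array 2 or KO_RA839 array 3 (up to 0.133 over 7 such settings). The other 32 lists did not pass (camera adjusted p = 0.163 to 0.973), except antigen presentation with the block at the preset correlation (median −0.12, adjusted p = 0.0421; adjusted p = 0.984 with an estimated correlation and no block). At an unadjusted p under 0.05 there were 679 genes. The count of 21 became 8 without WT_RA839 array 4, 9 without WT_RA839 array 3 or KO_RA839 array 1 and 10 without WT_DMSO array 1 or KO_RA839 array 4. It became 11 without WT_DMSO array 3, 12 without KO_DMSO array 1 or 4 or KO_RA839 array 3, and 66 (61 higher, 5 lower) with the replicate block within genotype.

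**Figure D2:**
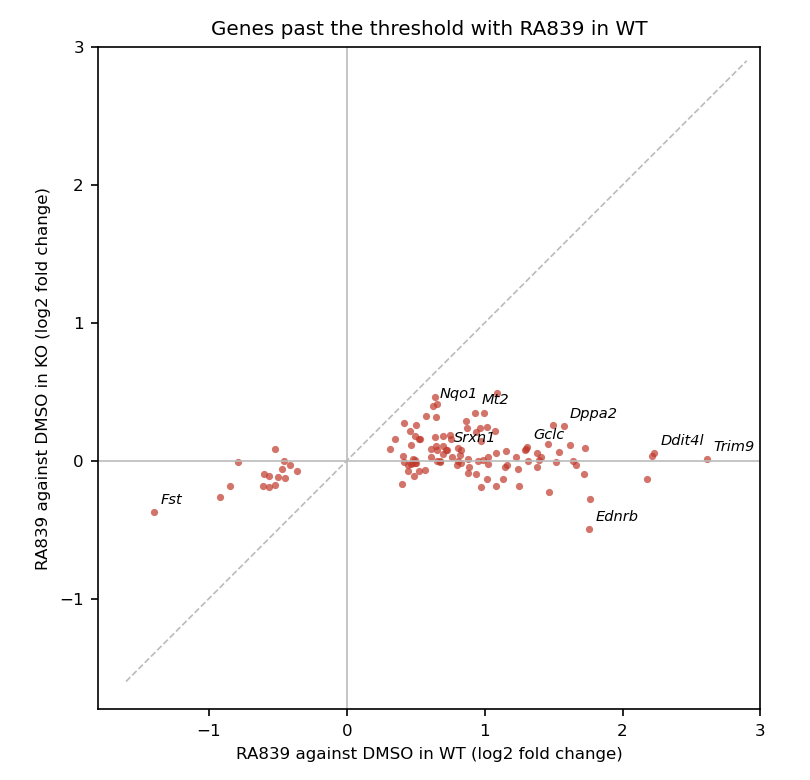
Each point is 1 of the 120 genes past the threshold with RA839 in WT, with its log2 fold change in WT on the horizontal axis and in KO on the vertical axis; the dashed line marks equal changes. The 104 genes raised in WT, chosen for that rise, have a median of 0.87 in WT and 0.04 in KO.

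Without RA839, KO macrophages differed broadly from WT. Other differences between the cultures of the genotypes cannot be told apart from the loss of Nrf2 on these arrays. In DMSO 2043 genes were higher and 2518 lower in KO than in WT, 25.1% of those tested, with 161 higher and 429 lower at least 2-fold. Among the brighter genes alone the balance turned, to 1528 higher and 1276 lower (54.5% higher against 44.8%). Besides Nfe2l2 the largest falls as measured were those of Ednrb (−5.56 ± 0.28), the retinol carrier Rbp4 (−5.19 ± 0.30), Nqo1 (28.4-fold lower, −4.83 ± 0.12) and the glutathione S-transferase Gsta3 (−4.72 ± 0.33). Next came the peptide hormone gene Cck (−4.43 ± 0.38), the cell cycle inhibitor Cdkn1c (−4.16 ± 0.38), Pdlim4 (−4.07 ± 0.12), Mpzl2 (−4.01 ± 0.46) and the xenobiotic-metabolizing Cyp1b1 (−4.00 ± 0.41). Their adjusted p-values were at most 1.99e-05, and falls to low RMA values, as for Ednrb and Mpzl2, are lower bounds. The largest rise was that of Rbm45, an RNA-binding protein gene (43-fold higher, 5.43 ± 0.06, adjusted p = 1.31e-17), on its only probe set and as the 8th tested gene from Nfe2l2 along the chromosome. It was followed by Slfn4 (3.40 ± 0.32), the carbonic anhydrase Car4 (3.36 ± 0.32), the arginase Arg1 (3.29 ± 0.77) and Ly6i (2.67 ± 0.40). Mex3b (2.52 ± 0.43), the oxygen sensor Egln3 (2.52 ± 0.22), the lysyl oxidase Lox (2.50 ± 0.60) and the costimulatory receptor Tnfrsf9 (2.50 ± 0.18) rose too, at adjusted p-values up to 0.00634. In all genes named here the 4 arrays of KO lay apart from the 4 of WT, as in 5375 genes in all, where chance gives 2.86%.

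Redox and detoxification genes were lower in KO, in lists that partly share members. Of 31 NRF2 core targets 28 fell and 0 rose (31 and 0 adjusted over the list alone), with a median of −1.47 (camera adjusted p = 5.28e-26; adjusted p = 5.64e-05 with an estimated correlation). Among them were Srxn1 (−2.84 ± 0.11), Slc7a11 (−2.59 ± 0.23), Gclm (−2.31 ± 0.20), Gstm1 (−1.87 ± 0.09), Txnrd1 (−1.47 ± 0.11) and Gclc (−1.22 ± 0.14), while Hmox1 was at −0.53 ± 0.21 (adjusted p = 0.0737). Of 18 genes of quinone detoxification 13 fell (15 fell and 1 rose adjusted over the list alone, median −0.62, camera adjusted p = 1.63e-09; adjusted p = 0.0144 with an estimated correlation), among them Ptgr1 (−1.82 ± 0.09). Of 20 glutathione S-transferases 12 fell and 2 rose (13 and 3 adjusted over the list alone, median −0.70, camera adjusted p = 4.69e-06; adjusted p = 0.00654 with an estimated correlation). Of 12 genes of the glutathione list 6 fell (6 adjusted over the list alone, median −0.39, camera adjusted p = 0.0014; adjusted p = 0.0144 with an estimated correlation), among them Gss (−1.55 ± 0.16). Of 11 thioredoxin and peroxiredoxin genes 5 fell (5 adjusted over the list alone, median −0.30, camera adjusted p = 0.000291; adjusted p = 0.0144 with an estimated correlation). Of 8 ABC export pumps Abcc1 (−1.65 ± 0.13), Abcc4 (−1.11 ± 0.14) and Abcb1a (−0.74 ± 0.13) fell (3 adjusted over the list alone, median −0.29, camera adjusted p = 0.0111; adjusted p = 0.0482 with an estimated correlation). Of 7 AhR targets 5 fell (5 adjusted over the list alone, median −1.39, camera adjusted p = 2.39e-05; adjusted p = 0.00654 with an estimated correlation), Cyp1b1 and Cyp1a1 (−1.39 ± 0.19) besides Nqo1 among them.

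Iron, NADPH and cholesterol synthesis genes were also lower in KO, by lists that passed at the preset correlation and were lost with an estimated one. Of 14 haem and iron genes 7 fell (8 adjusted over the list alone, median −0.25, camera adjusted p = 0.00134; adjusted p = 0.165 with an estimated correlation). Among them were the metal transporter Slc11a1 (−2.31 ± 0.14) and the biliverdin reductase Blvrb (−2.43 ± 0.22). Of 9 NADPH genes 4 fell (5 fell and 2 rose adjusted over the list alone, median −0.31, camera adjusted p = 0.02; adjusted p = 0.165 with an estimated correlation). Among them were the malic enzyme Me1 (−2.73 ± 0.15) and the transaldolase Taldo1 (−1.51 ± 0.09), and the list did not pass with only the groups compared, the brighter genes or the mean of probe sets (adjusted p up to 0.0732). Of 18 autophagy and lysosome genes 5 fell (5 adjusted over the list alone, median −0.16, camera adjusted p = 0.0287; adjusted p = 0.165 with an estimated correlation). Wipi1 (−0.70 ± 0.09) and Atg7 (−0.46 ± 0.07) were among them, and the list did not pass without WT_DMSO array 1 or KO_DMSO array 2 (adjusted p up to 0.264 over all 5 settings that ended its call). Of 20 cholesterol synthesis genes 7 fell (7 adjusted over the list alone, median −0.36, camera adjusted p = 0.02; adjusted p = 0.653 with an estimated correlation). Cyp51 (−0.89 ± 0.18) and Mvd (−0.66 ± 0.13) were among them, and the list did not pass without WT_DMSO array 2 or KO_DMSO array 1 (up to 0.217 over 4 such settings). Of 25 oxidative phosphorylation genes 5 fell (4 adjusted over the list alone, median −0.10, camera adjusted p = 0.0252; adjusted p = 0.556 with an estimated correlation). Ndufa2 (−0.35 ± 0.06) was among them, and the list did not pass without WT_DMSO array 3 (up to 0.0881 over 4 such settings). Other lipid genes went both ways, in lists that did not pass. Of 15 LXR and fatty acid synthesis genes 2 rose and 4 fell (median −0.33, camera adjusted p = 0.383), among them the lipid carrier Apoe (2.41 ± 0.74, lost without WT_DMSO array 1 or 2 or KO_DMSO array 1, 2 or 3, adjusted p up to 0.083), the fatty acid synthase Fasn (−1.48 ± 0.16) and the desaturase Scd2 (−1.44 ± 0.26). Of 15 fatty acid oxidation genes 1 rose and 2 fell (median 0.03, camera adjusted p = 0.729), the lipid receptor Cd36 (−0.97 ± 0.09) among the latter.

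Immune genes moved both ways in KO. Of 27 interferon-stimulated genes 1 rose and 1 fell (0 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.0111; adjusted p = 0.724 with an estimated correlation). Their mean level was 10.31 and 10.58 on KO_DMSO arrays 1 and 2, 9.16 and 9.17 on arrays 3 and 4, and 8.48 to 9.64 on the WT_DMSO arrays. The list did not pass without KO_DMSO array 1 or 2 or WT_DMSO array 2. Nor did it pass among the brighter genes or with KO_DMSO arrays 3 and 4 alone (camera adjusted p up to 0.85 over these 5 settings). Of 14 macrophage markers the lipopolysaccharide coreceptor Cd14 (1.83 ± 0.14) and the Fc receptor Fcgr1 (1.98 ± 0.40) rose and the integrin Itgam fell (−1.04 ± 0.13; 2 and 1 adjusted over the list alone). Of 20 HIF targets and glycolysis genes 4 rose, Egln3 and Vegfa (1.84 ± 0.20) among them, and 3 fell, Ndrg1 (−0.85 ± 0.14) among them (median 0.04, camera adjusted p = 0.383). Of 29 inflammatory mediators 4 rose and 3 fell (median 0.14, camera adjusted p = 0.383). Of 16 heat shock genes 3 rose, Hspa1b (1.61 ± 0.31) among them, and 3 fell, Hspb1 (−1.25 ± 0.19) among them (median −0.02, camera adjusted p = 0.858). The chemokine Ccl8 rose (2.06 ± 0.12). The calprotectin subunit S100a8 fell by 0.97 (± 0.09), in a list of 12 neutrophil markers of which 3 fell (3 adjusted over the list alone, median −0.31, camera adjusted p = 0.0586). In all, 24 lists, including all 9 marker lists, did not pass (camera adjusted p = 0.0586 to 0.858). KO_DMSO arrays 1 and 2 deviated together from the mean of KO_DMSO (r = 0.74 across genes), as did arrays 3 and 4 (r = 0.75), while pairs across them gave −0.91 to −0.85. With KO_DMSO arrays 1 and 2 alone there were 2918 genes past the threshold and with arrays 3 and 4 alone 3358. The Actb control differed by −0.43 in 3′ minus 5′ signal between KO and WT (exact two-sided permutation p = 0.0286, the smallest possible; adjusted p = 0.228 over 12 such tests).

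Keap1 siRNA raised genes of glutathione synthesis and glutathione S-transferases among many others. SiKeap1-1 raised 1578 genes and lowered 1163, and siKeap1-2 raised 1149 and lowered 889. Heph, a copper-dependent ferroxidase, rose most with each, by 5.03 ± 0.15 (32.6-fold, adjusted p = 1.1e-08) and 5.76 ± 0.15 (adjusted p = 2.24e-09). Other large rises with siKeap1-1 and siKeap1-2 were those of the glutathione S-transferases Gsta4 (3.09 ± 0.12 and 3.52 ± 0.12) and Gsta3 (2.23 ± 0.11 and 2.26 ± 0.11), the myeloid receptor Treml4 (4.08 ± 0.18 and 3.07 ± 0.18) and the interleukin-1 family member Il1f9 (3.37 ± 0.12 and 3.66 ± 0.12). Ednrb (3.18 ± 0.44 and 3.31 ± 0.44), the soluble epoxide hydrolase Ephx2 (2.82 ± 0.14 and 3.29 ± 0.14), Esm1 (2.82 ± 0.31 and 3.19 ± 0.31) and the platelet chemokine Ppbp (3.03 ± 0.35 with each) rose as well, at adjusted p-values up to 0.000477. Besides Keap1, large falls were those of the protease inhibitor Serpinb2 (−1.98 ± 0.37 and −1.89 ± 0.37) and the monocyte chemokines Ccl7 (−1.53 ± 0.29 and −2.04 ± 0.29) and Ccl2 (−1.49 ± 0.22 and −2.21 ± 0.22), at adjusted p-values up to 0.00603. With siKeap1-1 Lox (−1.97 ± 0.24) and the gelatinase Mmp9 (−1.89 ± 0.24) fell as well. In all these genes the 4 arrays of each siRNA lay apart from the 4 control arrays, as in 3641 and 3743 genes in all, where chance gives 2.86%.

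Among the core genes named in advance, Gclc rose by 2.05 ± 0.18 and 1.94 ± 0.18 with siKeap1-1 and siKeap1-2 and Gclm by 1.42 ± 0.12 and 1.33 ± 0.12. In the same order Nqo1 rose by 1.38 ± 0.13 and 1.28 ± 0.13, Slc7a11 by 1.25 ± 0.24 and 1.43 ± 0.24, and Txnrd1 by 0.46 ± 0.05 and 0.44 ± 0.05 (adjusted p up to 0.00446). Dimmer probe sets of Txnrd1 rose by 1.41 and 1.26 (1424486_a_at) and by 1.20 and 1.18 (1424487_x_at), while 1443536_at of Slc7a11 rose by 0.96 with siKeap1-1 and was at 0.20 with siKeap1-2 (adjusted p = 0.453). Hmox1 was at 0.40 ± 0.13 with siKeap1-1 (adjusted p = 0.0581, with the replicate block 0.00823) and at 0.18 ± 0.13 with siKeap1-2 (adjusted p = 0.442). Srxn1 rose with siKeap1-2 (0.55 ± 0.06, adjusted p = 0.000164) and was at 0.04 ± 0.06 with siKeap1-1 (adjusted p = 0.768), though its probe set 1451680_at rose there by 0.45 (adjusted p = 0.00696 over all probe sets). Nfe2l2 fell with siKeap1-1 (−0.48 ± 0.05, adjusted p = 0.000111) and with siKeap1-2 (−0.32 ± 0.05, adjusted p = 0.00238; 0.101 with all 28 arrays in 1 fit). Of 31 NRF2 core targets 23 rose with siKeap1-1 and 22 with siKeap1-2, and 0 fell by limma over all genes (26 and 24 rose adjusted over the list alone). Their medians were 0.56 (camera adjusted p = 1.86e-21; adjusted p = 0.0599 with an estimated correlation) and 0.71 (camera adjusted p = 7.25e-24; adjusted p = 0.0443 with an estimated correlation). Glutathione S-transferases had medians of 0.23 (9 rose and 2 fell, 11 and 2 adjusted over the list alone, adjusted p = 0.0398 with an estimated correlation) and 0.21 (9 rose, 10 adjusted over the list alone, adjusted p = 0.0195 with an estimated correlation). The glutathione list had medians of 0.35 (7 rose and 1 fell, 8 and 2 adjusted over the list alone, adjusted p = 0.0444 with an estimated correlation) and 0.29 (7 rose and 2 fell, 8 and 3 adjusted over the list alone, adjusted p = 0.0438 with an estimated correlation). Gss was at 1.94 ± 0.14 and 2.18 ± 0.14.

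**Figure D3:**
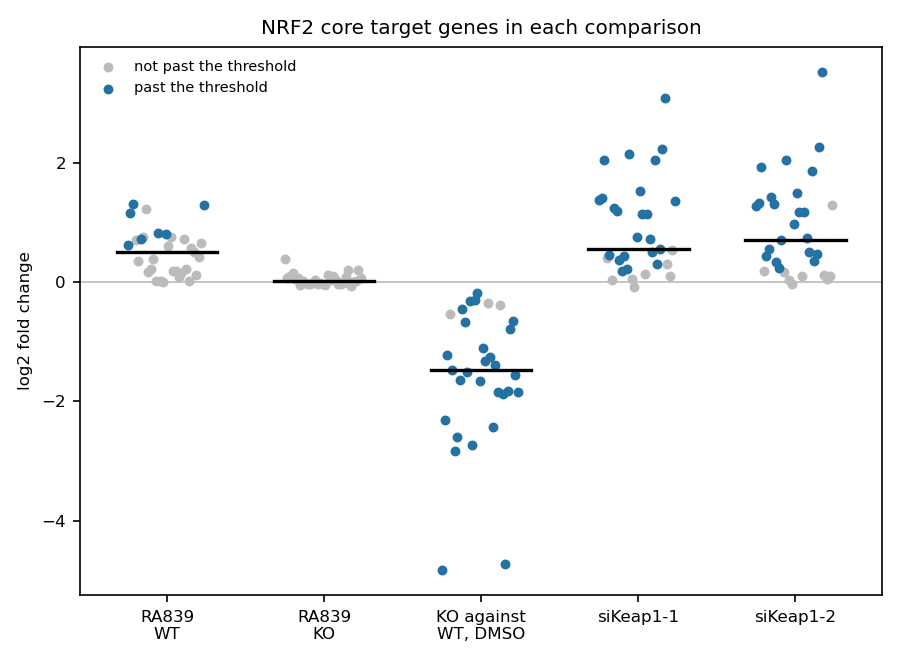
Each point is 1 of the 31 measured NRF2 core targets, with its log2 fold change on the vertical axis and 5 comparisons along the horizontal axis; blue points passed the threshold, grey points did not, and bars are medians. The medians are 0.51 for RA839 in WT, 0.02 for RA839 in KO, −1.47 for KO against WT in DMSO, 0.56 for siKeap1-1 and 0.71 for siKeap1-2.

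Other lists shifted upward with Keap1 siRNA by camera at the preset correlation, and most of those calls were lost with an estimated one. The quinone, NADPH, haem, AhR and ABC lists share members with the NRF2 core targets. Of 18 genes of quinone detoxification 12 and 8 rose (13 and 11 adjusted over the list alone, medians 0.57 and 0.54; adjusted p = 0.0599 and 0.0454 with an estimated correlation). Among them were the epoxide hydrolase Ephx1 (1.15 ± 0.07 and 1.17 ± 0.07) and pirin, Pir (2.05 ± 0.13 and 1.87 ± 0.13). Of 9 NADPH genes 4 rose with each siRNA (4 and 5 adjusted over the list alone, medians 0.16 and 0.17; adjusted p = 0.0654 and 0.0438 with an estimated correlation), with Me1 at 2.15 ± 0.19 and 2.05 ± 0.19. Of 14 haem and iron genes 6 rose with siKeap1-1, and 7 rose and 1 fell with siKeap1-2 (7 rose, and 7 rose and 3 fell, adjusted over the list alone, medians 0.24 and 0.22; adjusted p = 0.124 and 0.2 with an estimated correlation). Of 7 AhR targets 5 rose with each (5 and 6 adjusted over the list alone, medians 0.55 and 0.49; adjusted p = 0.0965 and 0.089 with an estimated correlation). Of 8 ABC export pumps 3 and 2 rose (5 rose, and 3 rose and 1 fell, adjusted over the list alone), with Abcc1 at 0.76 ± 0.11 and 0.97 ± 0.11. The medians were 0.56 (camera adjusted p = 0.00162; adjusted p = 0.129 with an estimated correlation) and 0.32 (camera adjusted p = 0.0615, with the replicate block 0.0115; adjusted p = 0.274 with an estimated correlation and no block). Of 31 proteasome subunits 14 rose and 1 fell with siKeap1-1 and 14 rose with siKeap1-2 (21 and 1, and 17, adjusted over the list alone, medians 0.16 with each; adjusted p = 0.211 and 0.2 with an estimated correlation), among them Psmd11 (0.52 ± 0.05 and 0.50 ± 0.05). With siKeap1-1 alone the unfolded protein response list passed (17 genes, 6 rose, 8 rose and 1 fell adjusted over the list alone, median 0.18, camera adjusted p = 0.0135; adjusted p = 0.567 with an estimated correlation), with Sdf2l1 at 0.55 ± 0.08. With siKeap1-2 alone the p53 list passed (15 genes, 6 rose and 1 fell, 7 and 2 adjusted over the list alone, median 0.21, camera adjusted p = 0.00392; adjusted p = 0.233 with an estimated correlation), with the death receptor Tnfrsf10b at 1.11 ± 0.11. So did HIF targets and glycolysis with siKeap1-2 (20 genes, 6 rose, 8 rose and 1 fell adjusted over the list alone, median 0.17, camera adjusted p = 0.000495; adjusted p = 0.207 with an estimated correlation), with adrenomedullin, Adm, at 3.47 ± 0.15.

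Downward shifts with Keap1 siRNA took in immune and proliferation genes. Of 27 interferon-stimulated genes 10 fell with siKeap1-1 and 15 with siKeap1-2 (12 and 19 adjusted over the list alone, medians −0.23 and −0.31, camera adjusted p = 5.41e-07 and 3.75e-12; adjusted p = 0.321 and 0.158 with an estimated correlation). Rtp4, for one, fell by 0.54 (± 0.06) and 0.66 (± 0.06), which did not pass with all 28 arrays in 1 fit (adjusted p = 0.788 and 0.738). Of 33 cell cycle genes 14 fell and 1 rose with siKeap1-1 and 13 fell with siKeap1-2 (19 and 1, and 23 and 1, adjusted over the list alone, medians −0.30 and −0.41; adjusted p = 0.124 and 0.0454 with an estimated correlation). Among them were Top2a with siKeap1-1 (−0.81 ± 0.14) and the spindle gene Tpx2 with siKeap1-2 (−0.67 ± 0.07). Of 14 macrophage markers 5 and 4 fell (6 adjusted over the list alone with each; medians −0.10 with each; adjusted p = 0.0965 and 0.0454 with an estimated correlation). Among them were the scavenger receptor Msr1 (−0.43 ± 0.04 and −0.57 ± 0.04) and Cd14 (−0.58 ± 0.12 and −0.91 ± 0.12). Of 18 antigen presentation genes 2 fell with each (3 and 2 adjusted over the list alone, medians −0.14 and −0.10; adjusted p = 0.0965 and 0.089 with an estimated correlation). The lists did not pass among the brighter genes alone or, for siKeap1-1, with all 28 arrays in 1 fit (adjusted p up to 0.0847 and 0.0538). Of 29 inflammatory mediators 5 rose and 9 fell with siKeap1-1 (6 and 10 adjusted over the list alone, camera adjusted p = 0.182). With siKeap1-2 2 rose and 9 fell (2 and 10 adjusted over the list alone, median −0.07, camera adjusted p = 0.00392; adjusted p = 0.204 with an estimated correlation). Cxcl3 rose (2.81 ± 0.34 and 3.31 ± 0.34) while Ccl4 fell (−1.05 ± 0.13 and −1.45 ± 0.13). With siKeap1-2 alone 3 more lists passed downward. They were cholesterol synthesis (20 genes, 6 fell, 11 adjusted over the list alone, median −0.22, adjusted p = 0.233 with an estimated correlation) with Idi1 at −0.71 ± 0.10 and heat shock (16 genes, 4 fell, 4 adjusted over the list alone, median −0.05, adjusted p = 0.207 with an estimated correlation) with Hspa1b at −1.13 ± 0.14. The third was immediate early genes (19 genes, 2 rose and 6 fell, 2 and 9 adjusted over the list alone, median −0.12, adjusted p = 0.158 with an estimated correlation), in which Fosl1 rose (2.11 ± 0.20). The heat shock and immediate early lists did not pass among the brighter genes alone (adjusted p = 0.105 and 0.0949).

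The remaining lists did not pass with siKeap1-1 (23 lists, camera adjusted p = 0.168 to 0.984, 8 of them marker lists) or siKeap1-2 (19 lists, 0.0615 to 0.999, 8 of them marker lists). With the replicate block, at the preset correlation, the megakaryocyte markers, led by Ppbp, also passed with siKeap1-1 (median 0.10, adjusted p = 0.0417) and siKeap1-2 (median 0.15, adjusted p = 0.0181). So did ATF4 targets (median 0.15, adjusted p = 0.0376), LXR and fatty acid synthesis (median −0.03, adjusted p = 0.0399) and oxidative phosphorylation (median 0.08, adjusted p = 0.0434) with siKeap1-2. Without the block an estimated correlation gave adjusted p = 0.396 and 0.233 for the markers and 0.659, 0.352 and 0.659 for the other lists. Centring each array on its median turned the direction of the counts, to 970 higher and 1604 lower with siKeap1-1 (37.7% higher against 57.6%) and 768 and 1073 with siKeap1-2 (41.7% against 56.4%). The replicate block gave 4371 and 3719 genes.

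The siRNAs differed from each other in 1356 genes, 650 higher and 706 lower with siKeap1-1. The skin-expressed gene Dmkn (1.77 ± 0.20, adjusted p = 0.000334), the surface receptor Slamf8 (1.57 ± 0.08, adjusted p = 2.39e-06), Ripor2 (1.38 ± 0.25) and Ypel4 (1.36 ± 0.16) were higher with siKeap1-1. The thyroid hormone receptor Thra (−1.25 ± 0.14, adjusted p = 0.000293), Smagp (−1.25 ± 0.08), the protein kinase A subunit Prkar2a (−1.18 ± 0.09) and Slc9a3r2 (−1.18 ± 0.10) were lower. Srxn1 was also lower (−0.51 ± 0.06, adjusted p = 0.000592). Gclc (0.12 ± 0.18), Gclm (0.08 ± 0.12), Nqo1 (0.10 ± 0.13), Txnrd1 (0.02 ± 0.05), Hmox1 (0.22 ± 0.13), Slc7a11 (−0.18 ± 0.24), Keap1 (−0.20 ± 0.08) and Nfe2l2 (−0.16 ± 0.05) did not differ past the threshold on the probe sets used (adjusted p = 0.112 to 0.887). The Slc7a11 probe set 1443536_at did differ, by 0.76 (adjusted p = 0.00773 over all probe sets). Lists that passed at the preset correlation were cholesterol synthesis (median 0.22, 4 higher and 1 lower, 10 and 2 adjusted over the list alone) and the unfolded protein response (0.12, 3 higher, 3 adjusted over the list alone). Heat shock (0.11, 2 higher, 2 adjusted over the list alone) and fatty acid oxidation (−0.21, 5 lower, 8 adjusted over the list alone) passed as well. Each was lost with an estimated correlation (adjusted p = 0.933, 0.933, 0.826 and 0.826 with an estimated correlation). The first and second did not pass without siKeap1-1 array 1 (adjusted p = 0.0702 and 0.067), nor the third without siKeap1-1 array 3 or among the brighter genes (up to 0.106). The other 33 lists, all 9 marker lists included, did not pass (camera adjusted p = 0.0702 to 0.95), and the block added, at the preset correlation, ATF4 targets (median −0.11, adjusted p = 0.00989) and p53 targets (median −0.08, adjusted p = 0.0123). Without the block an estimated correlation gave adjusted p = 0.933 for each. The count of 1356 became 849 without siKeap1-2 array 2 and 2665 with the replicate block, where the balance turned to 1390 higher and 1275 lower. It turned too without siKeap1-1 array 4 (544 and 538) and at 1.5-fold (150 and 126), and moved further down with arrays centred on their medians (452 and 701) and with all 28 arrays in 1 fit (233 and 368).

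Genes changed the same way by both Keap1 siRNAs numbered 1143, of which 750 rose and 393 fell. Independent lists of the same lengths would share 99.7 and 56.8. The siRNAs share their control arrays, which alone gave a mean correlation across genes of 0.417 in simulated unchanged groups (−0.628 to 0.932). The observed 0.736 lies inside that range, which leaves out the pairing of same-numbered arrays. The simulated covariance was 0.00746 (−0.00747 to 0.0364, observed 0.0576), with 0 shared genes in each of 100 simulations. With no true change the adjusted threshold leaves little to share. That 0 therefore sets no bound on the shared calls that common controls add. With the control arrays split between the siRNAs, 511 to 559 genes were shared at correlations of 0.52 to 0.59 and covariances of 0.0467 to 0.0506. Of the 750 raised genes 334 were lower in KO than in WT in DMSO (104 for independent lists) and 22 higher (84.2). Of the 393 lowered genes 98 were higher in KO (44.1) and 17 lower (54.4). Centring arrays on their medians gave 490 shared higher and 548 shared lower genes (47.2% higher against 65.6%), and the replicate block gave 2108 in all.

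RA839 and Keap1 siRNA changed many of the same genes. Of the 104 genes raised by RA839 in WT 70 rose with both siRNAs (4.29 for independent lists, Fisher's exact test p = 3.82e-72), and of the 16 lowered 5 fell with both (0.346, Fisher's exact test p = 1.65e-05). None was past the threshold in the opposite direction with both siRNAs (0 genes by limma in each direction). Genes are not independent replicates, so these p-values describe the lists. The shared genes with the highest mean change were Treml4, Cxcl3, Ednrb, Rasd2, Adm, Ddit4l, Trim9, the glycine transporter Slc6a9, the AP-1 subunit Fosl1 and Fam13a. For Ddit4l the values with RA839, siKeap1-1 and siKeap1-2 were 2.23 ± 0.21, 2.40 ± 0.17 and 2.37 ± 0.17, and for Fam13a they were 1.73 ± 0.23, 1.87 ± 0.16 and 2.19 ± 0.16. Rises of Adm and Trim9 with RA839 rest on probe sets that can match more than 1 transcript (0.16 and 0.21 without such probe sets). The siRNA rises of Trim9 did so too (1.86 and 2.31, without such probe sets 0.16 and 0.24, adjusted p = 0.335 and 0.154), while those of Adm (2.58 and 3.47) were smaller on its other probe set and passed (0.79 and 1.00). The RA839 calls of Treml4 (1.41, adjusted p = 0.0494) and Fosl1 (1.02, adjusted p = 0.0442) ended without any of 12 and 13 arrays (adjusted p up to 0.158 and 0.142). Fosl1 was at 0.49 over the mean of its probe sets (adjusted p = 0.0772). With only the groups compared Treml4, Cxcl3, Rasd2, Slc6a9 and Fosl1 did not pass (adjusted p = 0.0614 to 0.0928). The lowered shared genes were Ccl4, Sla (−0.85 ± 0.13, −0.82 ± 0.10 and −0.88 ± 0.10), Zc3h12d, the ubiquitin ligase Cblb and the kinase Prkch. The call of Zc3h12d ended without any of 6 arrays (adjusted p up to 0.0761) and that of Prkch without WT_RA839 array 4 (0.0551). With only the groups compared Zc3h12d, Cblb and Prkch did not pass (adjusted p = 0.0626 to 0.103). The 104 raised genes had medians of 0.87 with RA839, 0.81 with siKeap1-1 and 0.79 with siKeap1-2. Across all genes the RA839 response in WT correlated with the mean siKeap1 response at r = 0.36 (rho = 0.16), and among the 120 genes past the threshold at r = 0.75 (rho = 0.77), with 110 of the same sign. Of the 104 genes 65 were lower in KO than in WT in DMSO (14.4 for independent lists) and 7 higher (11.7). That pair of comparisons shares the WT_DMSO arrays, which in simulated unchanged groups gave 0 such genes and a covariance of −0.0165 to 0.0975, and the observed −0.0126 lies inside that range. On average the shared arrays moved both changes the same way, with a mean simulated correlation of 0.506 and covariance of 0.0189. They thus tend to make genes raised by RA839 and lower in KO rarer. The observed correlation was −0.129. Here too the simulated 0 sets no bound. With those arrays split, 43 to 66 genes were raised by RA839 and 29 to 50 of them were lower in KO (3.33 to 8.27 for independent lists), at correlations of −0.29 to −0.20 and covariances of −0.0347 to −0.022. The 75 shared genes became 49 without WT_RA839 array 4 and 199 with the replicate block within genotype.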

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

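The tests of Srxn1, of regroupings of the siRNA arrays within their numbers, of splits of the KO arrays and of a fall of Rbm45 with Nrf2 activation were chosen only after the results were seen; the other tests here were planned. Of 112 sets of 4 arrays tested for an array far from the others, 16 passed Dixon's critical value, where chance gives 5.6. The array median stood apart on WT_siControl array 3 (5.9566) and WT_siKeap1-1 array 4 (5.927). The mean correlation with its group stood apart on WT_RA839 array 2 (0.98866), as did its Gapdh 3′ minus 5′ signal (3.7387), and the Actb signal on WT_DMSO array 4 (1.9806). On arrays 4 of the siRNA experiment the female transcript Xist read 4.1643 with siControl, 4.4212 with siKeap1-1 and 5.1345 with siKeap1-2, and the Y-linked gene Eif2s3y read 12.668, 12.676 and 12.698. Arrays 1 to 3 of that experiment read 11.829 to 12.219 for Xist and 3.5589 to 3.9308 for Eif2s3y. The sex of the cells thus differed within each siRNA group and followed the number. On arrays 4 Nqo1 (13.326), Hmox1 (13.712) and Srxn1 (13.343) stood apart with siKeap1-1, Srxn1 (13.845) with siKeap1-2 and Gclc (10.475) with siControl.

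A test of the difference between the RA839 responses of WT and KO passed for 21 genes. Named by size they were Trim9 (2.60), Ednrb (2.26), Ddit4l (2.17), Comp (2.04), Cdcp1 (1.82), Gdap10 (1.70), Vegfd (1.69), Rabgap1l (1.43), Fam124a (1.38), Gss (1.33), Slc16a9 (1.32), Ampd3 (1.27), Gclc (1.21), Dnmt3l (1.20), Mtfr2 (1.04), Jade3 (1.03), Tshz1 (0.98), Chpf2 (0.83) and Phip (0.60), with 2 predicted genes at 1.26 and 1.16. The lists of NRF2 core targets (median 0.41), glutathione (0.14), quinone detoxification (0.19), NADPH supply (0.13) and ABC export pumps (0.22) passed camera for the same difference. Probe sets without a single gene name, which no comparison in the report used, passed the threshold in 9 cases for RA839 in WT, 1 for its difference between genotypes, 1743 for KO against WT, 176 for siKeap1-1, 138 for siKeap1-2 and 73 for siKeap1-1 against siKeap1-2.

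Other splits of the same arrays were counted for each comparison. For KO against WT 1 of 35 splits, the real one, gave as many genes (4561, highest other 1). So did 1 split each, the real one, for siKeap1-1 (1 of 35; 2741, highest other 0), siKeap1-2 (1 of 35; 2038, highest other 0) and siKeap1-1 against siKeap1-2 (1 of 35; 1356, highest other 1). The same held for 1143 genes changed by both siRNAs (1 of 100 drawn regroupings, highest other 0) and 75 genes shared with RA839 (1 of 100, highest other 0). These splits treat the arrays as exchangeable, which they were not. Same-numbered siRNA arrays deviated together, and KO_DMSO arrays 1 and 2 lay apart from 3 and 4 (−0.91 to −0.85 across them). Shares from these splits therefore do not exclude chance. The numbers pair the siRNA arrays. Regrouped only among arrays of the same number, 1 of 94 groupings gave as many genes changed by both siRNAs (highest other 437) and 1 of 100 as many shared with RA839 (highest other 0). Over regroupings that keep the numbers, chance was excluded for the genes changed by both siRNAs. For the genes shared with RA839, the WT compound arrays were regrouped at the same time as the siRNA arrays. That count can fall through the siRNA arrays alone, so it does not exclude chance for the RA839 side. For siKeap1-1, siKeap1-2 and their difference the other splits that part all 4 pairs gave 0 genes each, but 8 such splits are too few for a share under 5%. For RA839 in WT chance was not excluded: 2 of 35 splits gave as many genes (120, highest other 215). The split with 215 set arrays 1 and 2 against 3 and 4, which follows the replicate numbers and points to a structure of the arrays. It parted no same-numbered pair; among the 8 splits that part all 4 pairs, as the real one does, 1 gave as many and the others 0, and the replicate block within genotype gave 486 genes. For RA839 in KO all 35 splits gave at least the real count of 0, by limma and with 321 genes at an unadjusted p under 0.05, and the split of arrays 1 and 2 against 3 and 4 gave 2722. Those arrays too hold a structure that follows the numbers. For the difference between genotypes chance was not excluded: 6 of 100 regroupings gave as many genes (21, highest other 1592, again many times the real count). Of the 80 that part every pair 4 did (highest other 35), with 66 genes under the replicate block within genotype.

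Rbm45 was 43-fold higher in KO (WT 6.69 ± 0.04, KO 12.11 ± 0.04, SD, n = 4). A change around the altered Nfe2l2 locus that reaches most of its neighbours is argued against: 2 of the 10 nearest tested genes were past the threshold, beside 25.1% of all genes (exact hypergeometric p = 0.758). A predicted gene next to Nfe2l2 was 1 of them, at −1.45 ± 0.21 (limma adjusted p = 0.000157). Rbm45, the 8th tested gene, lies outside these 10. A local change that reaches only some genes therefore stays open. Whether Nrf2 holds Rbm45 down stays open, since activating the pathway left it at 0.14 with RA839, −0.02 with siKeap1-1 and 0.05 with siKeap1-2 (adjusted p = 0.469, 0.935 and 0.779). A fault of its 1 probe set also stays open, as there were 0 others to compare. A variant beside the altered allele that acts on Rbm45 alone was not tested.

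Srxn1 was lower with siKeap1-1 than with siKeap1-2 (−0.51). A weaker knockdown or weaker Nrf2 target response is argued against by the other 30 NRF2 core targets, whose median difference was 0.02 (quartiles −0.04 and 0.08). A fault of 1 probe set is argued against by its 3 other probe sets, all 3 of which differed the same way past the threshold (−1.11 to −0.49). An effect of an siRNA on Srxn1 apart from Keap1 stays open and was not tested, as the sequences are not given in the sources used here.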

How the results depend on the processing

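The block within genotype, the fits without arrays 2 of the WT compound groups, with KO_DMSO arrays 1 and 2 or 3 and 4 alone and without arrays 4 of the siRNA experiment were chosen only after the data were seen; the other alternatives were planned. A planned linear-scale alternative was not run, since the values are log2 values. RA839 in KO gave 0 genes in each alternative run, by limma (321 at an unadjusted p under 0.05 as first fitted). For RA839 in WT 120 genes became 306 with all 28 arrays in 1 fit, 65 with only the groups compared, 208 with array weights, 486 with the replicate block within genotype and 53 at an adjusted p under 0.01. Leaving out 1 array gave 72 (without WT_RA839 array 4) to 136 (without WT_RA839 array 2), and 74 without WT_DMSO array 1. For the difference between genotypes 21 became 45 with all 28 arrays, 8 without probe sets that can match more than 1 transcript, 43 with array weights, 66 with the replicate block within genotype and 5 at an adjusted p under 0.01. Without 1 array it was 8 (WT_RA839 array 4) to 26 (WT_RA839 array 2), with the other arrays that moved it by over 1.5 times named in the report.

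For KO against WT 4561 became 2804 among the brighter genes (fewer genes tested), 7890 over every probe set, 2918 with KO_DMSO arrays 1 and 2 alone (fewer arrays), 2459 at an adjusted p under 0.01 and 1879 at 1.5-fold, and 3577 to 5670 without 1 array. For siKeap1-1 2741 became 1470 with all 28 arrays, 4318 over every probe set, 4371 with the replicate block, 1468 at an adjusted p under 0.01 and 696 at 1.5-fold, and 2018 to 2685 without 1 array. For siKeap1-2 2038 became 1005 with all 28 arrays, 3064 over every probe set, 3243 with array weights, 3719 with the replicate block, 991 at an adjusted p under 0.01 and 561 at 1.5-fold, and 1361 to 2565 without 1 array. For siKeap1-1 against siKeap1-2 1356 became 601 with all 28 arrays, 845 with only the groups compared, 2665 with the replicate block, 868 without arrays 4, 593 at an adjusted p under 0.01 and 276 at 1.5-fold, and 849 (without siKeap1-2 array 2) to 1335 without 1 array. For genes changed by both siRNAs 1143 became 561 with all 28 arrays, 2108 with the replicate block, 1735 over every probe set, 564 at an adjusted p under 0.01, 335 at 1.5-fold, 559, 540 and 511 with the control arrays split, 2744 for the mean of both siRNAs against siControl and 794 to 1276 without 1 array. For the genes shared by RA839 and both siRNAs 75 became 120 with all 28 arrays, 43 with only the groups compared, 135 with array weights, 199 with the replicate block within genotype, 36 at an adjusted p under 0.01 and 49 (without WT_RA839 array 4) to 89 without 1 array. The cause was not tested for these changes except where given.

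The NRF2 core targets with siKeap1-1 had a median of 0.56 and did not pass with an estimated correlation (adjusted p = 0.0599). Among named genes and lists 4 reversed. Cell cycle genes with RA839 in KO, which did not pass as first fitted, ran from −0.10 (without KO_DMSO array 3) to 0.16 (without KO_RA839 array 3). Psma3 in KO against WT was at 0.06 and Rps6 with siKeap1-1 at −0.02 over the mean of their probe sets, and Masp1 with siKeap1-2 was at 0.25 without probe sets that can match more than 1 transcript; the cause was not tested. A block for the number across genotypes gave 152 genes for RA839 in WT, 104 of them among the 120, and 20 for the difference, 16 of them among the 21. It ended 6 calls of named genes in WT (Cxcl3, Slc51a, Ppargc1b, Ppard, Fosl1 and Treml4, adjusted p = 0.0541 to 0.104) and that of Cdcp1 for the difference (0.0506). The block within genotype, and the block for the number in the siRNA experiment, ended no call of a named gene or list. Beyond the results printed with a block in the report these added calls only of results the report does not name. Where the numbers do not pair the arrays, for KO against WT, a block for the number gave 4879 genes. Array signal limits what dim genes can show: RMA values of absent and weakly expressed genes overlap, so no gene is called absent here.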

Other observations

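The test of a response to RA839 in KO was chosen only after the pattern was seen, as were the genes listed in this part. The siRNAs moved 22 genes past the threshold in opposite directions, where independent lists of these lengths would give 77.1 and 73.5 for the opposed directions. The siRNAs share their control arrays, which alone makes opposed calls rarer, so independent lists are no reference for no change here. Slamf8, a receptor of the SLAM family, was at 0.54 with siKeap1-1 and −1.02 with siKeap1-2, and the innate immune regulator Nlrc3 at 0.45 and −0.57. The mitochondrial import subunit Timm17a was at 0.23 and −0.76, and the small GTPase Rab15 at 0.48 and −0.57. In the other direction lay Smagp (−0.79 and 0.46), the polycomb group gene Pcgf3 (−0.68 and 0.40) and the signal transducer Stat5b (−0.27 and 0.29).

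Interferon-stimulated genes differed among arrays of the same group in both genotypes. Their mean over 27 genes was 10.25, 10.54, 9.20 and 9.28 on KO_RA839 arrays 1 to 4 and 9.06, 8.33, 9.54 and 9.63 on WT_RA839 arrays 1 to 4. On the DMSO arrays with the same numbers it was 10.31, 10.58, 9.16 and 9.17 in KO and 9.05, 8.48, 9.64 and 9.54 in WT.

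Of the 104 genes raised by RA839 in WT, 16 were raised by neither siRNA, among them Dppa2 (1.57), Zfyve28 (0.99), the metallothionein Mt2 (0.93) and the keratin Krt10 (0.86). A hypothesis is that a response to RA839 that needs no Nrf2 may add to the change of these genes. In KO, whose arrays enter the choice of these genes only through the variance, their median was 0.26 against 0.65 in WT, with 14 of 16 genes and 4 of 4 same-numbered pairs of arrays higher (fry adjusted p = 0.00196; exact two-sided permutation p = 0.0286, the smallest 4 against 4 arrays can give). The other 88 genes had a median of 0.02 in KO (fry adjusted p = 0.277; 0.069 unadjusted with the replicate block), with 4 of 4 pairs higher too, by 0.01 to 0.07 against 0.10 to 0.32 for the 16. With genes chosen on the WT compound arrays alone and tested on the KO arrays alone, 8 genes were raised by neither siRNA, 2 of them among the 16. Their median was 0.64 in KO against 0.79 in WT, with 7 of 8 genes and 3 of 4 pairs higher, which did not pass (fry adjusted p = 0.318; exact permutation p = 0.114), so the explanation stays open. No single one of the 16 genes passed the threshold in KO by limma, so the hypothesis rests on the set. Of the genes that were not higher in KO, Gdap10 (1.47 in WT, −0.23 in KO) goes against it, with a difference between genotypes of 1.70 (adjusted p = 0.00183).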
